A study of Homo sapiens with 16 samples.

How the data were processed

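The series holds RNA sequencing of human blood neutrophils from 2 healthy donors, cultured for 4 h or 24 h under 4 conditions. The conditions were untreated (PBS, per the labels' protocols), TSLP, heat-killed methicillin-resistant Staphylococcus aureus (HKM, written HKSA in the protocol text), and HKM with TSLP. This gives 16 libraries in 8 groups, with 2 libraries (1 per donor) in each group. Libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq, per the labels' protocols. The series' design text gives the later time as 16 h, while the sample titles and file labels give 24 h; 24 h is used throughout.

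Per the labels' protocols, the authors called bases with CASAVA 1.8, aligned reads to hg19 with Bowtie, quantified genes with RSEM 1.2.21 and used edgeR for their own tests. The deposited table of each library lists 25593 genes by symbol, with no coordinates. The names of these tables carry a mark that no label explains, so genes or reads may have been filtered before deposit by an unknown rule. Its first measured column holds expected counts, which RSEM estimated for the authors by dividing reads that match several genes. A second deposited column holds TPM, which the authors' RSEM run scaled to gene length and to one fixed total per library. Another deposited column holds FPKM, the same estimate per length and sequenced fragments, per the file headers. The TPM and FPKM columns were not tested. Effective length and length differed by at most 0.01 in every table. The available reference annotation is of GRCh38, not hg19, so no coordinates are given and symbols stand as deposited.

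Expected counts were rounded to whole numbers. The 109 rows of XIST, TSIX and Y-linked genes were left out, which left 25484 genes. The tables hold 0 mitochondrially encoded genes. Library totals ran from 8502299 to 39004038 counts. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. A fold against a group with 0 counts is a lower bound computed against a floor of 3 counts over that group's libraries. Where a group had 1 to 3 counts, the ratio is given with its 95% interval (exact, Clopper-Pearson).

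Tests were run in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, glmQLFit and glmQLFTest) in 1 fit of the 8 group means, with 8 residual degrees of freedom and no donor term. The filter kept 16254 genes. The common biological coefficient of variation was 0.348. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over these genes. CPM values are TMM-scaled and given as group means over 2 donors; ± after a log2 fold change is its standard error, and a prior count of 2 was used for log CPM. Of the 14 comparisons, the interactions (TSLP by HKM at each time, HKM by time, TSLP by time) were tested as contrasts of the same fit.

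The labels number the donors 1 and 2 in every group, so libraries of a number come from the same donor. Deviations of the libraries from their group means correlated within donors at 0.36 to 0.79 (median 0.53, over 28 pairs of groups). The alternatives were the donor as a block, DESeq2 1.42.0, RLE size factors, no filter, a stricter filter of 5 CPM in 2 libraries, a fit of only the groups compared, and leaving out each library in turn. These choices, the gene lists and the rule for named genes were made before the data were examined. After the data had been seen, 3 alternatives were added: library size without a composition factor, leaving out the untreated 4 h library with most ribosomal RNA precursor together with the donor block, and a paired fit. In the paired fit each TSLP library is set against the library of the same donor, time and HKM state. It has 8 pairs, a common biological coefficient of variation of 0.085 and 4 residual degrees of freedom (7 where 1 common effect was fitted).

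Named genes are the 10 with the largest log2 fold change in each direction among called genes with the same direction in both donors and at least 5 CPM in the higher group. To these come up to 4 called members of each list by adjusted p, and a fixed panel reported whether called or not. HLA class I and highly polymorphic class II genes and receptor segments were not named. All called genes of the paired fit are named; that choice was made after their values were seen.

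There were 31 fixed lists. Those of function cover complement components, complement receptors, TSLP receptor signalling, STAT5 targets, TSLP-responsive dendritic cell chemokines and co-stimulatory genes, NF-kB cytokines, NF-kB feedback genes, interferon-stimulated genes, interferon-gamma targets, neutrophil granules, oxidative burst, pattern and Fc receptors, chemotaxis and adhesion, apoptosis and survival, glycolysis and hypoxia, oxidative phosphorylation, lipid mediators, cholesterol and lipid genes, antigen presentation, immediate-early and heat-shock genes, endoplasmic reticulum stress, and proliferation. Marker lists cover neutrophils, eosinophils, basophils with mast cells, monocytes with macrophages, T cells, B cells, NK cells, platelets and erythroid cells. A dendritic cell marker list was added after the data were seen. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. List p-values were adjusted over the 31 lists of a comparison. Figures were drawn with matplotlib 3.10.9.

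The steps were tested on simulated counts for the 16254 genes, of which 200 were changed. For HKM at 4 h, 5% of genes changed by a log2 of 1 and 54% of those changed by a log2 of 2 were recovered, with 5 false calls. For TSLP at 24 h the shares were 2% and 43%, with 2 false calls. For TSLP at 24 h in the paired fit they were 80% and 100%, with 15 false calls. In camera a raised list had an adjusted p of 7.31e-21, and 0 of 30 unchanged lists were called. The simulated genes were drawn independently of each other, so this cannot show whether the preset correlation holds for the real lists.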

Results

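Gene expression was measured by RNA sequencing in blood neutrophils of 2 healthy donors, cultured for 4 h or 24 h without treatment, with TSLP, with heat-killed MRSA (HKM), or with both. TSLP, thymic stromal lymphopoietin, is an epithelial cytokine that signals through a receptor made of CRLF2 and IL7R. Each of the 8 groups held 2 libraries, 1 per donor. Library totals were 33761772 to 36809237 counts for donor 1 at 4 h and 26605271 to 39004038 at 24 h. For donor 2 they were 19555545 to 28256132 at 4 h and 8502299 to 16229725 at 24 h. Both receptor chains were detected: in untreated cells CRLF2 had 2.47 CPM at 4 h and 3.07 CPM at 24 h, and IL7R had 4.71 and 17.1 CPM. The libraries do not resolve cells and also hold markers of other cell types, T cells among them. Which cells these receptor reads came from is thus not known. The first principal component held 45.4% of the variance and separated the times. The next held 29.8% and separated libraries with and without HKM. The one after held 13.1% and separated the donors. With and without TSLP, libraries of the same donor, time and HKM state correlated at 0.98 to 0.994 across genes, which are not independent replicates. The untreated 4 h library of donor 2 stood apart by RNA45S5, the ribosomal RNA precursor, which took 5.74% of its counts.

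The comparison of TSLP with untreated cells at 24 h, and of HKM with TSLP against HKM alone, asks what TSLP changes in neutrophils at rest and during contact with bacteria. The genes called in the fit paired by donor included the chemokine genes CCL22, CCL17 and CCL19. CCL22, a ligand of the T-cell receptor CCR4, rose with TSLP by a log2 of 1.36 ± 0.21 without HKM and 2.10 ± 0.19 with HKM (n = 2 pairs each; edgeR adjusted p = 0.0374 and 0.000236). CCL17, another CCR4 ligand, was at least 29.5-fold higher without HKM and at least 52.3-fold higher with HKM, with 0 counts in the libraries without TSLP. FSCN1, the actin-bundling protein fascin of mature dendritic cells, rose by 1.26 ± 0.13 and 1.38 ± 0.13 (adjusted p = 0.00259 and 0.000236). CCL19, a ligand of CCR7, was at least 11.1-fold higher without HKM and rose by 2.69 ± 0.25 with HKM. It was not silent before in donor 2, with 3.04 CPM untreated and 8.16 CPM with HKM at 4 h. Both exceed that donor's levels with TSLP at 24 h (1.58 and 4.45 CPM). In donor 1 the 4 h levels were 0.0333 and 1.22 CPM, against 0.254 and 3.28 CPM with TSLP at 24 h.

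The levels moved in both donors. Without HKM, CCL22 went from 6.31 to 10.7 CPM in donor 1 and from 9.92 to 40.3 CPM in donor 2. With HKM it went from 14.6 to 56.3 CPM and from 14 to 68 CPM. FSCN1 went from 14.2 to 27.5 CPM and from 35.7 to 106 CPM without HKM, and from 37.1 to 90.5 CPM and from 43.9 to 123 CPM with HKM. C10orf10, a gene known to respond to fasting and hypoxia, rose by 3.76 ± 0.51 and 3.29 ± 0.35, at no more than 2.73 CPM. Without HKM, TSLP also raised UBD, a ubiquitin-like modifier (3.32 ± 0.44), the transcript WFDC21P (1.75 ± 0.29) and CDKN1A, the cell cycle inhibitor p21 (0.86 ± 0.12). SLC38A2, an amino acid transporter, fell by 0.58. With HKM it raised IL2RA, the alpha chain of the interleukin 2 receptor and a STAT5 target, by 1.64 ± 0.24 (from 3.83 to 10.4 and from 2.54 to 9.92 CPM). It also raised FLT3, the receptor for FLT3 ligand (1.17 ± 0.19), TUBB2B, a tubulin (5.34 ± 0.59), and NES, the filament protein nestin (3.63 ± 0.53). TUBB2B and NES were low at 24 h, with at most 3.15 and 1.48 CPM in a library. TNFRSF11B, the RANKL decoy receptor osteoprotegerin, had 104 counts against 3, a ratio of 37.8 (12.6 to 186). CD302, a C-type lectin, fell by 1.06, and SLC2A4, a glucose transporter, fell by 0.75. The read-through transcript ARL2-SNX15 was called as well, but its counts came from donor 1 alone and share reads with ARL2 and SNX15. Without HKM, TUBB2B, NES and TNFRSF11B also stood higher with TSLP but were not called (2.81 ± 0.89, 3.44 ± 1.09 and 2.96 ± 0.65). FLT3 differed by 0.13 there.

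**Figure D1:**
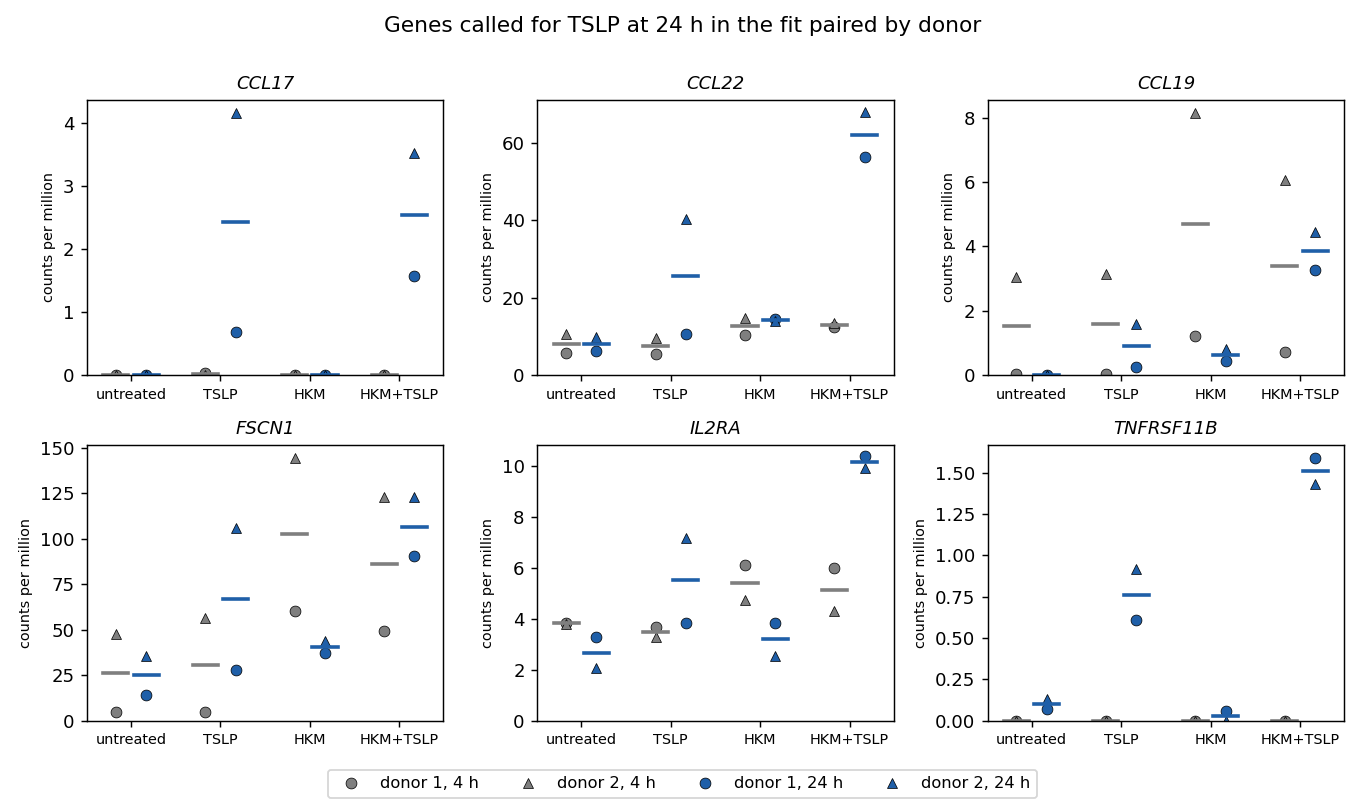
TMM-scaled CPM of 6 genes called for TSLP at 24 h in the fit paired by donor, under the 4 conditions at 4 h (grey) and 24 h (blue); each point is 1 library, circles are donor 1, triangles donor 2 and bars the mean of the 2 donors. CCL22 at 24 h lies at 6.31 and 9.92 CPM in untreated cells and at 56.3 and 68 CPM with HKM and TSLP.

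These calls came from the paired fit, which was added after the data had been seen: 8 genes rose and 1 fell without HKM, and 11 rose and 2 fell with HKM. Without the pair of donor 1 the counts were 55 and 11, and without that of donor 2, 41 and 10. Those counts rest on 1 pair, assumed to vary like the others, and do not show that the same genes stayed. Of the 9 and 13 genes, 5 were in both sets, in the same direction, where independent sets of these sizes share 0.00554. The sets are not independent, as they come from the same fit, with 1 spread estimate per gene and the same 2 donors. In the 8-group edgeR fit 0 genes passed in either comparison (61 and 48 genes at an unadjusted p under 0.05), with the donor block 0 (138 and 154), and DESeq2 called 0 (38 and 32). CCL22 and CCL17 did pass in the 8-group fit when HKM with TSLP was set against untreated cells (CCL22 by 2.94 ± 0.56, adjusted p = 0.0111, and CCL17 at least 42-fold, adjusted p = 0.0387). DESeq2 called CCL22 there and not CCL17 (adjusted p = 7.49e-06 and 0.53). That comparison also holds the effect of HKM, so it is no test of TSLP alone. With HKM alone at 24 h CCL22 differed by 0.82 ± 0.53 and CCL17 had 0 counts. The 8-group fit called 1114 genes in it, which eases the adjusted threshold for each gene.

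Complement genes are what the study's title concerns. At 24 h C3 differed in the fit paired by donor by a log2 of -0.16 ± 0.10 without HKM and 0.08 ± 0.09 with HKM (adjusted p = 1 and 0.904). In the 8-group fit C5AR1, the C5a receptor, differed by 0.17 and 0.06, and CR1 by 0.25 and 0.00. The list of complement components (20 measured) had 0 genes that rose and 0 that fell with TSLP in both states, 0 also when adjusted over the list alone. The list of complement receptors (14 measured) had the same counts. In simulated counts the 8-group fit recovered 2% of genes changed by a log2 of 1, so its counts of 0 do not show that the levels stayed. The paired fit recovered 80% of such genes without HKM, and no gene it called is on either list. Its values for C3, C5AR1 and CR1 argue against a TSLP change of a log2 of 1 at 24 h, for these genes alone.

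Among gene groups at 24 h, the dendritic cell chemokine and co-stimulatory list (13 measured) stood higher with TSLP without HKM (camera adjusted p = 0.00171; adjusted p = 0.981 with an estimated correlation). In it 1 gene rose when adjusted over the list alone and 0 over all genes. With HKM the values were 2 genes and adjusted p = 0.000157 (adjusted p = 0.996 with an estimated correlation). In the paired fit 3 and 4 of its genes rose when adjusted over the list alone. STAT5 targets (18 measured), the usual readout of TSLP receptor signalling, stood higher in both states (adjusted p = 0.0383 and 0.00744; adjusted p = 0.429 and 0.373 with an estimated correlation). When adjusted over the list alone, 0 of them rose without HKM and 1 with HKM. IL2RA, on this list, was called with HKM in the paired fit. CISH, SOCS2 and PIM1 were not called in either fit: CISH differed by 0.50 and 0.46, SOCS2 by 0.25 and 0.82, and PIM1 by 0.12 and 0.14.

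Interferon-stimulated genes (40 measured) stood lower with TSLP in HKM-treated cells at 24 h (camera adjusted p = 0.000157; adjusted p = 0.996 with an estimated correlation), with 0 genes called over all genes. In the paired fit 14 fell when adjusted over the list alone, 28 were lower in both donors and 0 were higher in both. CXCL10, counted among the 14 and under 1 CPM, was lower in donor 1 and higher in donor 2. IFIT1, an antiviral RNA-binding protein, changed from 16.8 to 10.3 CPM (-0.71 ± 0.12, adjusted p = 0.00194 over the list alone), and MX1, an antiviral GTPase, from 34.2 to 24.2 CPM (-0.51 ± 0.11). The interaction test of this list, TSLP with HKM against TSLP without, had a camera adjusted p of 0.00222 (adjusted p = 0.968 with an estimated correlation). Without HKM, interferon-gamma targets (23 measured) stood higher with TSLP (adjusted p = 0.0182; adjusted p = 0.981 with an estimated correlation). Platelet markers (11 measured) stood lower (adjusted p = 0.0182; adjusted p = 0.311 with an estimated correlation). Both had 0 genes called, over all genes and over the list alone.

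At 4 h CCL22 differed by a log2 of -0.12 without HKM and 0.05 with HKM in the paired fit, and FSCN1 by 0.15 and -0.26. CCL19 differed by 0.05 and -0.52 and UBD by 1.55 and 0.46, and none of these genes was called. In the 8-group edgeR fit 0 genes passed for TSLP alone (53 at an unadjusted p under 0.05) and 0 for TSLP with HKM (57), and DESeq2 called 0 (35 and 39). No list passed in the 8-group fit. The paired fit called 0 genes without HKM (270 at an unadjusted p under 0.05) and FSBP with HKM, at least 38-fold lower (108 counts against 0), a gene nested in another and so uncertain, with all of its counts from donor 1. The change of the TSLP effect from 4 h to 24 h was called for 0 genes by edgeR (71 at an unadjusted p under 0.05), 0 by DESeq2 (47) and 0 in the paired fit (355).

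The interaction of TSLP with HKM asks whether TSLP acts otherwise in cells that meet bacteria. It was called for 0 genes at 4 h (76 at an unadjusted p under 0.05 in edgeR; DESeq2 0, 47) and 0 at 24 h (38; DESeq2 0, 22), and the paired fit called 0 at both times (408 and 586). Genes called in 1 state alone, among them CDKN1A, UBD, IL2RA, FLT3, TUBB2B, NES and TNFRSF11B, are thus not shown to differ between the states. Over both times and HKM states, the 8-group fit called 0 genes for TSLP (68 at an unadjusted p under 0.05, and by DESeq2 0 and 40). The paired fit with 1 common effect called 6, all higher: C10orf10, CCL17, TNFRSF11B, NES, TUBB2B and ARL2-SNX15 (adjusted p = 0.000356 to 0.045). At 4 h C10orf10, TNFRSF11B and NES had 0 CPM in every library, and CCL17 and TUBB2B at most 0.0343 and 0.109 CPM. Their calls thus rest on 24 h. ARL2-SNX15 had 1.545 CPM at 4 h in the TSLP library of donor 2. Swapping libraries within pairs did not exclude chance for this count (3 of 50 splits, the real one included, called as many). STAT5 targets stood higher on the average over both times and HKM states (adjusted p = 0.000196, and 0.0965 with an estimated correlation). Across the 16254 genes, which are not independent replicates, the TSLP changes without and with HKM correlated at -0.029 (Spearman 0.038) at 4 h and 0.144 (Spearman 0.135) at 24 h. At 24 h it was 0.004 (Spearman -0.136) within donor 1 and 0.221 (Spearman 0.313) within donor 2.

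Heat-killed MRSA against untreated cells at 4 h asks how neutrophils respond to the bacteria alone. Cytokine genes were among those that rose most. CSF3, the granulocyte growth factor G-CSF, had 357 counts against 1, a ratio of 434 (77.3 to 17200; edgeR adjusted p = 0.00471). CCL20, a chemokine for CCR6-bearing cells, rose by a log2 of 6.26 ± 1.07, and CXCL2, a neutrophil chemokine, rose from 6.46 to 227 CPM (5.15 ± 1.25; n = 2 donors per group). OSM, an interleukin 6 family cytokine, rose by 3.44 ± 0.47, VEGFA, the angiogenic growth factor, by 4.52 ± 0.69 and TNF by 2.01 ± 0.56. CXCR2, the receptor for interleukin 8, went from 3527 to 692 CPM (-2.35 ± 0.65, adjusted p = 0.0462), and F2RL1, a protease-activated receptor, from 123 to 7.51 CPM (-4.04 ± 0.93).

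Of the NF-kB cytokine list (30 measured) 14 rose and 0 fell, and 19 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.06e-14; adjusted p = 0.343 with an estimated correlation). IL1B (2.70 ± 1.13, adjusted p = 0.168) and CXCL8 (1.68 ± 0.48, adjusted p = 0.0516) were not called in this fit. The donor block called CXCL8 (adjusted p = 0.0256, and 0.0676 for IL1B), and DESeq2 called both (adjusted p = 0.00208 for CXCL8 and 0.0286 for IL1B). The donors differed at the start: donor 2 stood higher than donor 1 in untreated cells at 4 h in 27 of these 30 genes, and the list's median change with HKM was 4.59 in donor 1 and 2.03 in donor 2. Among endoplasmic reticulum stress genes (22 measured) 7 rose and 0 fell, 12 and 0 when adjusted over the list alone (adjusted p = 2.85e-06; adjusted p = 0.0823 with an estimated correlation). XBP1, the transcription factor of the unfolded protein response, rose from 34.8 to 301 CPM and TRIB3 by 2.23 ± 0.41. Cholesterol genes (26 measured) had 7 that rose and 1 that fell, the same over the list alone (adjusted p = 0.000296; adjusted p = 0.0823 with an estimated correlation). They included LSS, lanosterol synthase (3.39 ± 0.41), MVD of the mevalonate pathway (2.47 ± 0.47), and INSIG1, a sterol sensor (2.42 ± 0.46). Interferon-stimulated genes had 6 of 40 that rose and 0 that fell, 17 and 0 over the list alone (adjusted p = 6.74e-08; adjusted p = 0.6 with an estimated correlation). IFIT1 rose by 1.94 ± 0.30 and ISG15 by 1.99 ± 0.36. With library size only, 2 of the 40 rose. Oxidative burst genes had 6 of 26 that rose and 0 that fell, 9 and 1 over the list alone (adjusted p = 0.00569; adjusted p = 0.609 with an estimated correlation). The risen members named were SLC7A11, GCLC, TXN and TXNRD1, which serve glutathione and thioredoxin, not the oxidase. Of immediate-early genes (31 measured) 3 rose and 1 fell, 7 and 1 over the list alone (adjusted p = 0.00445; adjusted p = 0.67 with an estimated correlation).

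For the TSLP pathway, HKM raised CRLF2 from 2.47 to 6.47 CPM (1.39 ± 0.34, adjusted p = 0.0286), while IL7R differed by 0.10. STAT5A, the kinase LYN and 1 more of the 15 receptor signalling genes rose and 2 fell, 3 and 3 over the list alone. The list's median, 0.13, turned to -0.15 with library size only. STAT5 targets had 3 of 18 that rose and 0 that fell, 4 and 1 over the list alone (adjusted p = 0.0191; adjusted p = 0.286 with an estimated correlation), with SOCS3 at 4.27 ± 0.70. The dendritic cell chemokine list had 0 of 13 called, also over the list alone (adjusted p = 0.0194; adjusted p = 0.704 with an estimated correlation). Of NF-kB feedback genes (21 measured) 0 were called, also over the list alone, and 8 rose with the donor block (adjusted p = 1.02e-06; adjusted p = 0.673 with an estimated correlation). Complement components had 0 of 20 called. Complement receptors had 0 of 14 called and 2 that rose over the list alone. C5AR1 had 1164 CPM untreated and 2404 CPM with HKM (1.05 ± 0.31, adjusted p = 0.0561, and 0.0213 with the donor block). C3 had 116 and 294 CPM (1.34 ± 1.31, adjusted p = 0.639), and CR1 differed by -0.18.

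Among the largest changes outside the lists, GJB2, the gap junction protein connexin 26, rose from 0.359 to 51.1 CPM (7.30 ± 1.05) and NCR3LG1, a ligand of an NK-cell receptor, from 10.4 to 498 CPM. PPAP2B, a lipid phosphatase, rose from 5.11 to 198 CPM and MGLL, monoacylglycerol lipase, from 2.58 to 96.9 CPM. PHLDA2, CCL18 and FXYD6 rose by 5.30, 5.23 and 4.96. Of the lower genes, IMPA2, an inositol monophosphatase, went from 111 to 6.40 CPM, CHST13, a chondroitin sulfotransferase, from 10.7 to 0.714 CPM, and CLDN9, a claudin, from 12.5 to 0.94 CPM. TIGD3, DHRS9, NUDT16, MPZL1, BRI3BP and LRRC75A fell by 3.57 to 3.19.

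In all, HKM raised 789 genes and lowered 750 at 4 h, against 1710 and 1712 with the donor block and 1336 and 1132 by DESeq2. With library size only, 573 rose and 1623 fell (26.1% higher, against 51.3%), as the median of all genes moved to -0.255. The count was 57 without the untreated library of donor 1, 203 and 285 without the HKM library of donor 1 and of donor 2, 1541 without the untreated library of donor 2, and 0 in a fit of these 2 groups alone (3221 at an unadjusted p under 0.05). With the donor block and without that last library, 1648 rose and 1656 fell.

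**Figure D2:**
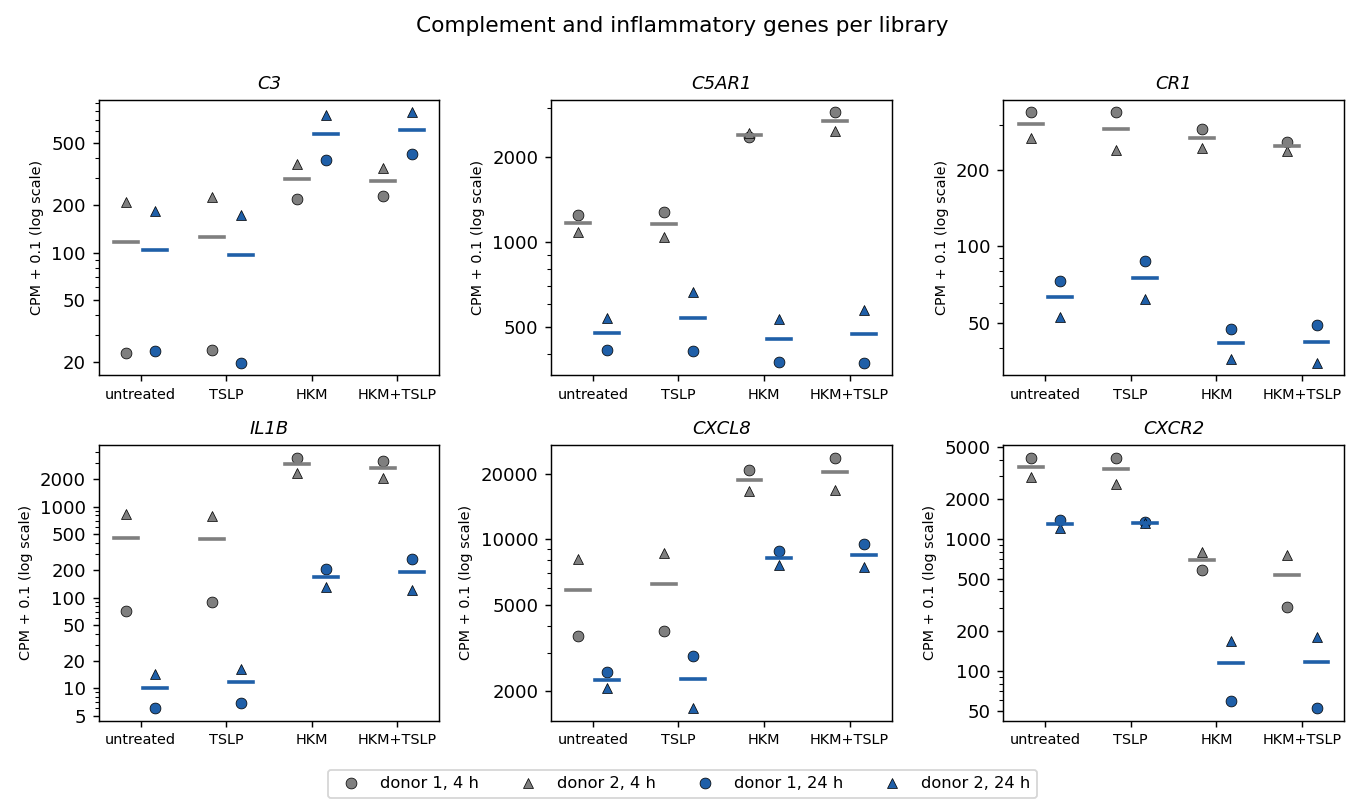
TMM-scaled CPM plus 0.1 (log axis) of 3 complement and 3 inflammatory genes under the 4 conditions at 4 h (grey) and 24 h (blue); each point is 1 library, circles are donor 1, triangles donor 2 and bars the mean of the 2 donors. C5AR1 has means of 1164 CPM in untreated and 2404 CPM in HKM-treated cells at 4 h.

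At 24 h, HKM against untreated cells again moved cytokines upward. CSF1, the macrophage growth factor, went from 13.8 to 369 CPM (4.74 ± 0.63, adjusted p = 0.00194), and TNFSF15, a TNF family ligand, from 4.21 to 241 CPM. CCL3, an inflammatory chemokine, rose by 6.84 ± 1.79 (17.0 to 1932 CPM; near-identical copies make its count uncertain), and CCL23 had a ratio of 452 (154 to 2190). FFAR1, a fatty acid receptor, had 1223 counts against 1, a ratio of 982 (176 to 38800), and CYP17A1, a steroid synthesis enzyme, rose by 7.27 ± 0.89 (0.898 to 125 CPM). CXCR2 fell by 3.51 (1299 to 114 CPM). MME, the surface peptidase CD10, fell by 3.80 (281 to 20.3 CPM) and FN1, fibronectin, by 7.74 (58.0 to 0.244 CPM). The donors differed widely in untreated FN1 (SD 65.5 CPM), with changes of -7.99 in donor 1 and -5.69 in donor 2.

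NF-kB cytokines had 15 of 30 that rose and 0 that fell, 25 and 1 over the list alone and 24 and 1 with the donor block (adjusted p = 1.21e-14; adjusted p = 0.443 with an estimated correlation). CXCL8 rose by 1.87 ± 0.48, CXCL1 by 2.54 ± 0.38 and TNF by 2.57 ± 0.57. IL6 was at least 75-fold higher but not called (adjusted p = 0.0979, and 0.0476 with the donor block), nor was IL1B (4.07 ± 1.21, adjusted p = 0.0743, and 0.0257 with the donor block). DESeq2 called both (adjusted p = 0.00375 and 0.00079). NF-kB feedback genes had 1 of 21 that rose and 0 that fell, 2 and 0 over the list alone (adjusted p = 2.32e-06; adjusted p = 0.78 with an estimated correlation), and 8 rose with the donor block. STAT5 targets had 5 of 18 that rose and 0 that fell, 7 and 0 over the list alone (adjusted p = 0.000247; adjusted p = 0.116 with an estimated correlation). SOCS3 rose by 4.81 ± 0.73, OSM from 15.1 to 121 CPM and PIM1, a survival kinase, by 1.43 ± 0.32. The dendritic cell chemokine and co-stimulatory list had 4 of 13 that rose and 0 that fell, 6 and 0 over the list alone (adjusted p = 0.000633; adjusted p = 0.706 with an estimated correlation). The 4 were the T-cell ligands CD80 (4.29 ± 1.04), CD274 (3.97 ± 0.76) and PDCD1LG2, and CXCL8. CCL22 differed by 0.82 ± 0.53 (adjusted p = 0.491) and CCL17 had 0 counts in both groups. Interferon-stimulated genes had 7 of 40 that rose and 0 that fell, 9 and 1 over the list alone (adjusted p = 0.00296; adjusted p = 0.803 with an estimated correlation). Oxidative burst genes had 7 of 26 that rose and 0 that fell, 9 and 1 over the list alone (adjusted p = 0.000918; adjusted p = 0.586 with an estimated correlation). Endoplasmic reticulum stress genes had 2 of 22 that rose and 0 that fell, 9 and 0 over the list alone (adjusted p = 0.00296; adjusted p = 0.371 with an estimated correlation). Immediate-early genes had 3 of 31 that rose and 0 that fell, 5 and 0 over the list alone (adjusted p = 0.00102; adjusted p = 0.706 with an estimated correlation).

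Mature neutrophil markers had 2 of 24 that rose and 7 that fell, 4 and 11 over the list alone (adjusted p = 0.000526; adjusted p = 0.78 with an estimated correlation). Among them MNDA, a nuclear protein of myeloid cells, fell by 3.39 and VNN2, a pantetheinase, by 2.52, while FFAR2, a short-chain fatty acid receptor, rose by 1.65 ± 0.21. Of complement receptors (14 measured) ITGAX, the integrin chain of complement receptor CR4, rose by 1.42 ± 0.24 and CD46, a complement regulator, fell by 1.21, with the same counts over the list alone. Complement components had 1 of 20 that fell and 0 that rose, 3 and 0 over the list alone, the first being C4BPA, at least 4.56-fold lower (11 counts against 0). C3 had 103 and 574 CPM (2.48 ± 1.36, adjusted p = 0.382, and 0.02 with the donor block), and CR1 differed by -0.59 ± 0.28 (adjusted p = 0.285, and 0.0276 with the donor block). Genes best known from other cells were among the highest risers: CD22, a sialic acid lectin of B cells, went from 7.21 to 589 CPM, and OLIG2, on the eosinophil list, from 1.08 to 81.0 CPM. The rest of the B-cell list had 0 of its other genes called, and of the eosinophil list likewise 0. CACNB4, ANGPT1, KAZN, CA4, TIGD3, LRRC75A, MANSC1 and IMPA2 fell by 4.63 to 3.76.

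HKM raised 727 genes and lowered 307 at 24 h, against 1544 and 966 with the donor block and 1080 and 646 by DESeq2. With library size only 528 rose and 503 fell (51.2% higher, against 70.3%), as the median of all genes moved to -0.18. The count was 115 without the untreated library of donor 1, 293 without that of donor 2, 291 and 390 without the HKM library of donor 1 and of donor 2, and 334 (281 higher, 53 lower) in a fit of these 2 groups alone.

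The 2 times shared much of the HKM response. Of the raised genes 390 were called at both times (35.3 for independent lists), of the lowered genes 153 (14.2), and 0 were called in opposite directions, with no library shared between the comparisons. With the donor block the counts were 887 (162.4), 520 (101.7) and 7. The changes correlated at 0.62 across genes, which are not independent replicates. CCR1, a chemokine receptor, changed by 1.21 ± 0.23 at 4 h and 3.04 ± 0.24 at 24 h, a difference of 1.83 ± 0.32, and NLRP3, an inflammasome sensor, had a difference of -3.46 ± 0.50. The difference itself was called for 0 genes in edgeR (1126 at an unadjusted p under 0.05), for 41 with the donor block (23 higher and 18 lower at 24 h) and for 99 by DESeq2 (44 higher, 55 lower). Cholesterol genes had a smaller HKM change at 24 h than at 4 h (camera adjusted p = 0.000148; adjusted p = 0.103 with an estimated correlation), with 0 genes called and 3 that fell over the list alone. Mature neutrophil markers stood lower in the same test (adjusted p = 0.000106; adjusted p = 0.878 with an estimated correlation). So did interferon-stimulated genes (adjusted p = 0.023; adjusted p = 0.878 with an estimated correlation), with 0 genes called in either and, over the list alone, 1 neutrophil marker that fell. Library size only moved the median of all genes to 0.126.

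HKM with TSLP against untreated cells measures both stimuli together. At 4 h CSF3 had a ratio of 667 (119 to 26400), and GJB2 rose by 7.82 ± 1.06, CCL20 by 7.12 and CXCL2 by 5.63 (n = 2 donors per group). CXCR2 fell by 2.72 and F2RL1 by 4.18. C5AR1 went from 1164 to 2685 CPM (1.21 ± 0.31, edgeR adjusted p = 0.0262), and CRLF2 rose by 1.75 and CXCL8 from 5856 to 20330 CPM. C3 differed by 1.31 (adjusted p = 0.619). C5AR1 was called here and not with HKM alone, but the difference between these, HKM with TSLP against HKM, was 0.16 ± 0.30 (adjusted p = 1). NF-kB cytokines had 16 of 30 that rose and 0 that fell, 19 and 1 over the list alone (adjusted p = 2.63e-13; adjusted p = 0.397 with an estimated correlation). Endoplasmic reticulum stress genes had 9 of 22 that rose and 0 that fell, and complement receptors 2 of 14 and 0. In all 1043 genes rose and 1130 fell (2005 and 2141 with the donor block, 1516 and 1470 by DESeq2). With library size only 782 rose and 2163 fell (26.6% higher, against 48%), as the median of all genes moved to -0.265. The count was 363 without the untreated library and 353 without the treated library of donor 1, and 0 in a fit of these 2 groups alone (3371 at an unadjusted p under 0.05).

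At 24 h this comparison brought the TSLP genes and the bacterial response together. CCL22 went from 8.12 to 62.1 CPM, CCL17 was at least 42-fold higher and IL2RA rose by 1.91 ± 0.35 (adjusted p = 0.00945). CD302 fell by 4.46, much of it with HKM alone. HKM alone took CD302 from 158 to 6.51 CPM in donor 1 and from 156.5 to 25.9 CPM in donor 2. TSLP with HKM against HKM changed it by -1.06 in the paired fit. FFAR1 had a ratio of 1170 (209 to 46100), and CYP17A1 rose by 7.57, CD22 by 6.50, CSF1 by 5.04 and SOCS3 by 5.07. FN1 fell by 6.58, CACNB4 by 4.91, ANGPT1 by 4.65 and MME by 4.09. STAT5 targets had 6 of 18 that rose and 0 that fell, 10 and 0 over the list alone (adjusted p = 1.87e-06; adjusted p = 0.0354 with an estimated correlation). Of the 434 list tests of all comparisons, this was the 1 that passed with an estimated correlation, and 65 passed at the preset one. The dendritic cell chemokine and co-stimulatory list had 5 of 13 that rose and 0 that fell, 8 and 0 over the list alone (adjusted p = 6.36e-07; adjusted p = 0.315 with an estimated correlation). Oxidative burst genes had 9 of 26 that rose and 0 that fell (adjusted p = 0.000205; adjusted p = 0.345 with an estimated correlation). Interferon-stimulated genes had 6 of 40 that rose and 1 that fell, 7 and 1 over the list alone (adjusted p = 0.13). C3 had a change of 2.55 (adjusted p = 0.366, and 0.0169 with the donor block), ITGAX rose by 1.60, and CD46 and SERPING1, the C1 inhibitor, fell by 1.46 and 1.19. In all 784 genes rose and 330 fell (1604 and 1001 with the donor block, 1100 and 641 by DESeq2). With library size only 585 rose and 522 fell (52.8% higher, against 70.4%), as the median of all genes moved to -0.204. The count was 167 without the untreated library of donor 1, 332 without that of donor 2, 312 and 665 without the treated library of donor 1 and of donor 2, and 251 (221 higher, 30 lower) in a fit of these 2 groups alone.

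**Figure D3:**
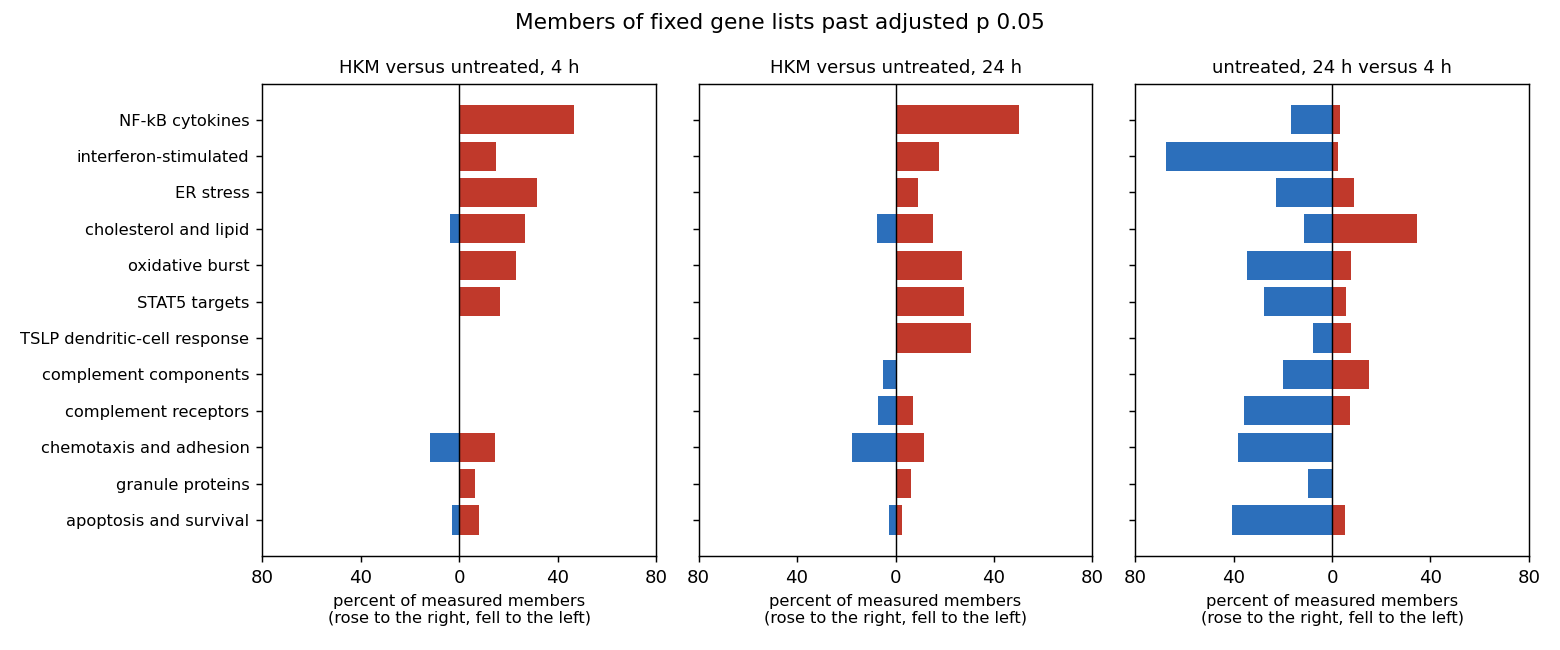
Share of the measured members of 12 fixed lists that rose (red, to the right) or fell (blue, to the left) in the 8-group edgeR fit at an adjusted p under 0.05, for 3 comparisons of 2 donors per group. Interferon-stimulated genes had 6 and 7 of 40 that rose with HKM at 4 h and 24 h, and 27 of 40 that fell with time, 22 with library size only.

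Untreated cells at 24 h against 4 h show what changed in culture alone. MRC1, the mannose receptor, had 815 counts against 1, a ratio of 669 (120 to 26500). CD163, the haemoglobin scavenger receptor, rose from 0.971 to 27.9 CPM (edgeR adjusted p = 0.00272), and GPNMB, a lysosomal glycoprotein, from 0.294 to 83.0 CPM (7.97 ± 1.09; n = 2 donors per group). SLCO2B1, an organic anion transporter, was at least 123-fold higher, CCL2, the monocyte chemokine, rose by 5.27 ± 0.94, and FABP5, a fatty acid binding protein, by 4.67 ± 0.40. Of the genes that fell, IL1B went from 448 to 10.1 CPM (-5.48 ± 1.29) and PTGS2, cyclooxygenase 2, from 280 to 13.0 CPM. ALPL, the neutrophil alkaline phosphatase, went from 274 to 8.97 CPM and IFIT1 from 73.5 to 4.22 CPM. IL7R rose from 4.71 to 17.1 CPM (1.86 ± 0.26, adjusted p = 0.00154), and CRLF2 differed by 0.31. T-cell markers had the higher sum at 24 h as well (69.6 and 181 CPM), and the cell source of the IL7R reads was not tested.

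Interferon-stimulated genes had 27 of 40 that fell and 1 that rose, 31 and 1 over the list alone (adjusted p = 4.24e-12; adjusted p = 0.184 with an estimated correlation). Interferon-gamma targets had 16 of 23 that fell and 1 that rose, the same over the list alone (adjusted p = 1.99e-05; adjusted p = 0.184 with an estimated correlation). Of the TSLP receptor signalling genes 10 of 15 fell and 1 rose, the same over the list alone (adjusted p = 0.000729; adjusted p = 0.112 with an estimated correlation), with STAT5A from 377 to 75.8 CPM. NF-kB feedback genes had 8 of 21 that fell and 0 that rose, 14 and 0 over the list alone (adjusted p = 0.00253; adjusted p = 0.684 with an estimated correlation). NF-kB cytokines had 5 of 30 that fell and 1 that rose, 4 and 1 over the list alone and 10 and 2 with the donor block (adjusted p = 0.0272; adjusted p = 0.738 with an estimated correlation). Chemotaxis and adhesion genes had 13 of 34 that fell and 0 that rose, 13 and 2 over the list alone (adjusted p = 0.000667; adjusted p = 0.184 with an estimated correlation). Apoptosis and survival genes had 15 of 37 that fell and 2 that rose, 17 and 2 over the list alone (adjusted p = 0.00183; adjusted p = 0.184 with an estimated correlation). The last included both the death receptor FAS, which fell by 3.68, and the survival protein MCL1, which fell by 1.48, while BCL2 rose by 2.01. Complement receptors had 5 of 14 that fell and 1 that rose, 5 and 2 over the list alone (adjusted p = 0.0541). CR1, the C3b receptor, went from 302 to 62.9 CPM (-2.26 ± 0.29) and C5AR1 from 1164 to 475 CPM (-1.29 ± 0.31), and ITGAX and CD46 fell by 1.58 and 1.32. Complement components had 4 of 20 that fell and 3 that rose, 4 and 4 over the list alone. The list's median turned from -0.24 to 0.69 with library size only. C1QB rose by 4.75 and C1QC was at least 27.6-fold higher, while CFD, complement factor D, fell by 2.18 and SERPING1 by 2.00.

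Markers of several other cell types rose with time. Monocyte and macrophage markers had 9 of 20 that rose and 0 that fell, 11 and 0 over the list alone (adjusted p = 0.000169; adjusted p = 0.153 with an estimated correlation). B-cell markers had 7 of 16 that rose and 0 that fell, 9 and 0 over the list alone (adjusted p = 0.000729; adjusted p = 0.501 with an estimated correlation). T-cell markers had 6 of 20 that rose and 0 that fell, the same over the list alone and 13 with the donor block (adjusted p = 0.0139; adjusted p = 0.313 with an estimated correlation). NK-cell markers had 1 of 16 that rose and 0 that fell, the same over the list alone and 14 with the donor block (adjusted p = 0.0329; adjusted p = 0.738 with an estimated correlation). Basophil and mast cell markers had 4 of 11 that rose and 0 that fell, 5 and 0 over the list alone (adjusted p = 0.00721; adjusted p = 0.184 with an estimated correlation). Mature neutrophil markers had 6 of 24 that fell and 0 that rose, the same over the list alone (adjusted p = 0.00183; adjusted p = 0.555 with an estimated correlation). Summed over each list, untreated cells had 31250 CPM of neutrophil markers at 4 h and 13320 CPM at 24 h, and 234 and 547 CPM of monocyte and macrophage markers. The sums were 69.6 and 181 CPM for T-cell markers, 116 and 158 CPM for B-cell markers and 431 and 1126 CPM for NK-cell markers. They were 31.1 and 70.6 CPM for basophil and mast cell markers and 191 and 257 CPM for erythroid markers. Eosinophil markers had the lower sum at 24 h, 207 and 164 CPM, in both donors. Platelet markers had means of 14.2 and 11.4 CPM, but the donors went apart. Their sum fell from 17.4 to 9.36 CPM in donor 1 and rose from 11.1 to 13.5 CPM in donor 2.

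**Figure D4:**
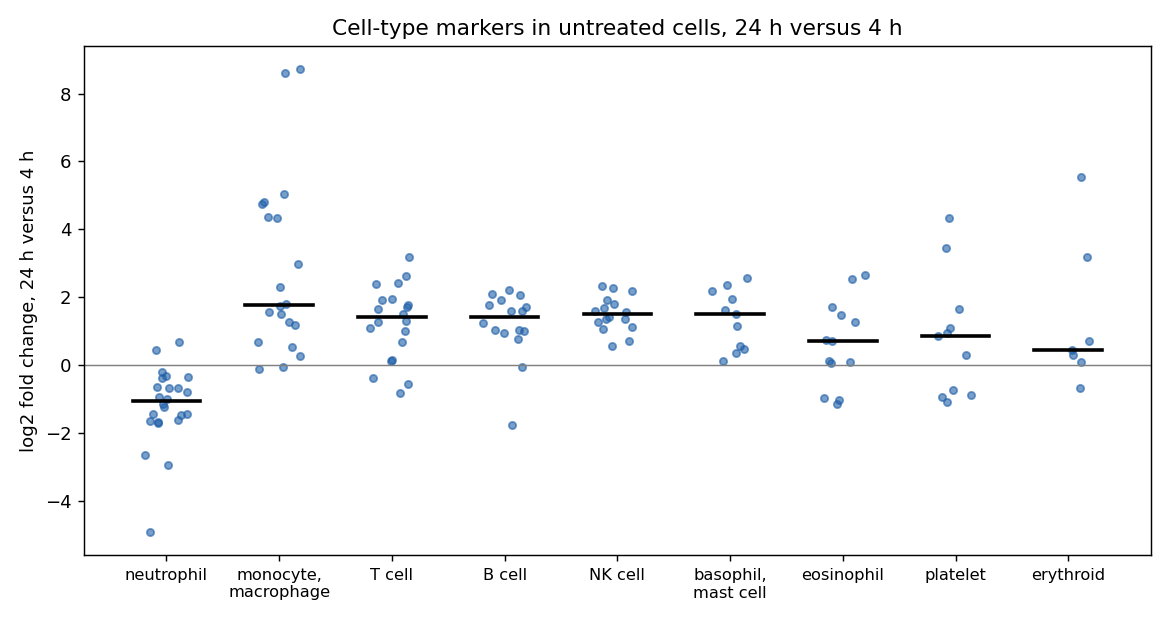
Log2 fold change of single marker genes (points, spread sideways for sight) of 9 cell types in untreated cells at 24 h against 4 h, with the list medians as bars; values of genes with 0 counts at 4 h depend on the prior count. Medians are -1.07 for neutrophil markers, -0.18 with library size only, and 1.77, 1.41, 1.41, 1.49 and 1.52 for monocyte and macrophage, T-cell, B-cell, NK-cell and basophil markers.

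With time 2156 genes rose and 2554 fell (4172 and 3982 with the donor block, 2568 and 2794 by DESeq2). The balance rested on the composition factor: with library size only 6442 rose and 413 fell (94% higher, against 45.8%) and the median of all genes moved to 0.855. Under it the interferon-stimulated list had a median of -1.76 and 22 genes that fell, and the neutrophil marker list a median of -0.18. The count was 2944 without the untreated 4 h library of donor 1 and 1672 without that of donor 2, 1725 and 1863 without the untreated 24 h library of donor 1 and of donor 2, and 1681 (841 higher, 840 lower) in a fit of these 2 groups alone.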

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

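The donor block behind these values was chosen before the data were examined, and the fit without 1 untreated library was added after the result had been seen. The response to HKM differed between the times. With the donor as a block, edgeR called the change of the HKM effect from 4 h to 24 h for 41 genes, 23 with a higher and 18 with a lower effect at 24 h, the direction being the same in both donors for each gene named here. Among the lower ones, the inflammasome sensor NLRP3 had a difference of -3.46, and TLR4, the lipopolysaccharide receptor, -1.94. The pantetheinases VNN2 and VNN3 had -1.90 and -1.48, and NCR1, an NK-cell receptor, -1.44.

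The chemokine receptor CCR1 had a higher HKM effect at 24 h, by 1.83. Other genes with a higher effect included the potassium channel subunit KCNS1 (3.69), FAM27B (3.40, one of several similar copies and so uncertain), MACC1 (3.31), TXLNB (2.69), DFNB31 (2.30), the SLAM family receptor CD84 (2.17), PRKAG2, a subunit of AMP-activated kinase (2.13), ETV5 (2.08), the lysosomal transporter SLC15A4 (2.04) and the histone deacetylase HDAC4 (1.95). Other genes with a lower effect included LYPD3 (-5.18), ZNF165 (-4.06), FRMD4B (-3.73), ACP6 (-2.67), LIPN (-2.27), FAM19A2 (-2.25) and LSMEM1 (-1.81). Without the donor block 0 genes passed (1126 at an unadjusted p under 0.05), and DESeq2 called 99. With the block and without the untreated 4 h library of donor 2, 5 were higher and 5 lower. No explanation of these differences was tested.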

How the results depend on the processing

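The composition-free scaling, the paired fit and the fit without 1 untreated library were chosen after results had been seen. With the donor block the calls rose to 3422 for HKM at 4 h, 4146 for HKM with TSLP against untreated cells at 4 h, 2510 and 2605 for the same at 24 h, 8154 for time and 41 for the HKM effect by time; the block removes the donors' offsets, with a biological coefficient of variation of 0.211 against 0.348. Every call of the 8-group fit was kept in its direction, the TSLP counts stayed at 0, and 79 of the gene list tests passed against 65. With the block and without the untreated 4 h library of donor 2, the counts were 3304, 3848 and 10 for the first, the second and the HKM effect by time. The paired fit gave 9 calls for TSLP at 24 h and 13 with HKM, 1 for TSLP with HKM at 4 h and 6 for the average, since pairs vary less (0.085). Without the pair of donor 1 these first 2 counts were 55 and 11, and without that of donor 2, 41 and 10. These counts rest on 1 pair, assumed to vary like the others, and do not show that the same genes stayed.

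DESeq2 called 2468 genes for HKM at 4 h, 1726 at 24 h, 1741 for HKM with TSLP against untreated cells at 24 h and 99 for the HKM effect by time; the cause was not tested. In fits of only the groups compared, with fewer libraries to estimate the spread, the counts were 0 for HKM and 0 for HKM with TSLP against untreated cells at 4 h, 334 and 251 at 24 h, and 1681 for time. Of the values of single named genes, these fits ended 312 calls, added 2 and left 471 values on the same side of the threshold. Without a filter the HKM effect by time was called for 4 genes. Of the list tests 1 passed with an estimated correlation and 37 with fry, which tests another hypothesis. The correlation of the TSLP changes at 4 h was -0.089 under the stricter filter and 0.003 within donor 1; at 24 h it was 0.251 (Spearman 0.254) under that filter, 0.004 (Spearman -0.136) within donor 1 and 0.221 (Spearman 0.313) within donor 2. The cause was not tested. RLE size factors and the stricter filter left every count within 1.5 times of its value. With library size only, 3 genes of the time comparison reversed: BNIP3L (0.102), HSPA5 (0.08) and DNAJC3 (0.031), as that scaling moves the median of all genes to 0.855.

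Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave 57 to 1541 calls for HKM at 4 h, 353 to 2075 for HKM with TSLP against untreated cells at 4 h, 115 to 390 and 167 to 665 for these at 24 h, 1672 to 2944 for time, and 0 to 1 for TSLP with HKM at 24 h (1 without the treated library of donor 1). The other TSLP counts, the interactions and the HKM effect by time stayed at 0. Of the values of single named genes, leaving out a library ended 864 calls, added 7 and left 3337 values, called or not, on the same side of the threshold, and the donor block ended 0 and added 57. Low counts limit CCL17, CCL19, TNFRSF11B, C10orf10, NES, TUBB2B and ARL2-SNX15. In the 8-group fit the standard errors of C3 and IL1B exceed a log2 of 1 in the HKM comparisons.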

Other observations

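The tests weighed in this part were chosen after the results had been seen, except the split test of the 8-group fit. HKM moved metabolic and sensing genes in both directions at 4 h. Of glycolysis and hypoxia genes (35 measured) 3 rose and 4 fell, 4 and 6 when adjusted over the list alone: PFKFB3, a driver of glycolysis, rose by a log2 of 1.70 ± 0.31, while the oxygen sensor EGLN1 fell by 2.78. Pattern and Fc receptors (33 measured) had 3 that rose and 4 that fell, 5 and 6 over the list alone, with TLR2 from 381 to 1263 CPM, CASP1 at 1.30 ± 0.22, TLR6 from 502 to 124 CPM and the inflammasome adaptor PYCARD from 105 to 21.6 CPM. Chemotaxis and adhesion genes (34 measured) had 5 that rose and 4 that fell, 5 and 8 over the list alone, with the hyaluronan receptor CD44 at 2.20 ± 0.37 and S1PR4, a sphingosine phosphate receptor, at -2.58 ± 0.48. Apoptosis and survival genes (37 measured) had 3 that rose and 1 that fell, 4 and 2 over the list alone; BCL2A1, a survival protein, rose by 2.56 ± 0.63 and PMAIP1, a death protein, by 1.71 ± 0.23, and the list's median turned below 0 with library size only. Granule genes (31 measured) had 2 that rose and 0 that fell, the same over the list alone: CTSD and CD63, both lysosomal. At 24 h that list again had 2 that rose and 0 that fell, 2 and 1 over the list alone, with a median of -0.57 and a mean of -0.00, while camera pointed upward (adjusted p = 0.729). In the other lists HKM at 4 h raised 1 of 35 oxidative phosphorylation genes (UQCRC2, 0 over the list alone), 1 of 19 lipid mediator genes (PTGS2), 1 of 17 antigen presentation genes (IFI30) and 1 of 20 proliferation genes (MCM2), each of the last 3 also over its list alone. Interferon-gamma targets had 1 of 23 that rose and 1 that fell, the same over the list alone.

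In untreated cells from 4 h to 24 h, cholesterol and lipid genes had 9 of 26 that rose and 3 that fell, 11 and 4 over the list alone (camera adjusted p = 0.0241; adjusted p = 0.184 with an estimated correlation). CD36, a lipid scavenger receptor, rose by 3.19 ± 0.45 and PLIN2, a lipid droplet coat protein, by 2.00 ± 0.28, while the cholesterol exporter ABCA1 fell from 271 to 18.5 CPM. Antigen presentation genes had 3 of 17 that rose and 2 that fell, the same over the list alone, with the lysosomal proteases LGMN and CTSL at 3.19 ± 0.34 and 2.66 ± 0.60. Oxidative phosphorylation genes had 8 of 35 that rose and 1 that fell, 5 and 1 over the list alone, and glycolysis and hypoxia genes 4 and 8 of 35, 4 and 9 over the list alone; lipid mediators had 3 of 19 that rose and 2 that fell, 3 and 3 over the list alone. The medians of these last 3 lists, -0.11, -0.19 and -0.14, turned to 0.79, 0.69 and 0.78 with library size only. Proliferation genes had 2 of 20 that rose and 0 that fell, 1 and 0 over the list alone. Granule genes had 0 of 31 that rose and 3 that fell, 0 and 2 over the list alone and 19 and 5 with the donor block. Eosinophil (13 measured), platelet (11) and erythroid markers (7) had 1 gene each that rose, with 1, 0 and 0 over the lists alone.

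A candidate explanation of the CCL17, CCL22, CCL19 and FSCN1 rise is a TSLP response of cells in the culture, either the neutrophils or a few dendritic cells, as these genes are known from dendritic cells. For chance calls among low counts, the sets without and with HKM shared 5 genes, where independent sets would share 0.00554 (binomial p = 1.11e-14). The sets come from the same fit, with 1 spread estimate per gene and the same 2 donors. That p assumes independence, so it cannot decide about chance. Of the shared genes, CCL22 and FSCN1 were not at low counts (untreated 24 h libraries 6.31 and 9.92 CPM, and 14.2 and 35.7 CPM). Both rose in both donors and both states. A larger share of monocytes in the TSLP libraries is argued against. Without HKM the same holds for a larger share of dendritic cells, but only of those that carry the markers used. Only markers with a mean of at least 1 CPM at 24 h were used. The 14 monocyte markers had a median TSLP change of 0.013 (SD 0.154) without HKM and -0.018 (SD 0.127) with HKM. The 8 dendritic cell markers had -0.062 (SD 0.246) without HKM and 0.112 (SD 0.441) with HKM. The smallest rises among the called genes were 0.861 without HKM, that of CDKN1A, and 1.167 with HKM. FLT3, 1 of the 8 dendritic cell markers, was itself called with HKM and is that smallest rise of 1.167. With HKM the markers' median was thus set against their own highest member, so the test cannot decide there for dendritic cells. A response of a small, constant share of dendritic cells stays open: 9 of the 13 dendritic cell markers reached 1 CPM in untreated cells at 24 h, with FCER1A at 5.27, ZBTB46 at 4.55 and FLT3 at 4.43 CPM, 4 of the 13 are on another list, and the labels name no sort that would remove such cells. A neutrophil response to TSLP, the biological explanation the design gives, cannot be told apart from it, since the libraries do not resolve cells.

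For the average over times and HKM states, swapping libraries within the 8 pairs tested whether chance can be excluded. In the paired fit 3 of 50 drawn splits, the real one included, called as many genes as the real 6, and the highest of the others called 9, so chance is not excluded for this count. The splits differ from the real one in which member of a pair counts as treated, and most of them set pairs with a TSLP response at 24 h against each other. In the 8-group fit the real count was 0, which every split reaches, so its 10 of 10 drawn splits (highest other 0) decide nothing about chance.

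The rise of markers of several other cell types in untreated cells at 24 h may come from a lower share of neutrophil RNA, as when neutrophils die or lose RNA in culture. This cannot be told apart for the cell types other than monocytes. The medians of their 7 lists lay 1.086 apart, from 0.43 to 1.52. Over their 94 markers, a permutation test of the Kruskal-Wallis statistic between the lists did not pass (p = 0.288). The bootstrap upper bound of that gap exceeded the median of all these markers, 1.26, so the lists are too small to show whether they moved alike. For monocytes and macrophages the test cannot decide whether a lower neutrophil share is the whole cause. Of 20 markers 7 rose by more than 3.35, a limit set from the lymphocyte and basophil markers, where 0.5 would by chance (binomial p = 3.55e-07). CD163 reached 27.9 and LIPA 115 CPM at 24 h. That p assumes a normal spread and independent genes, and low counts at 4 h raise some folds (MRC1 1 count, C1QC 0 counts). HBD, GP1BB and CLEC1B, erythroid and platelet markers, passed the limit too (5.55, 4.35 and 3.46). The median of the 20 was 1.77, and that of the lymphocyte and basophil markers 1.52. Of the 20, 5 are on another list and 7 had at least 5 CPM in untreated cells at 4 h. The TMM factors did not create the rise, as they lowered it. The median over 83 markers was 2.435 (SD 1.581) with library size only, against 1.562 with TMM. Library size only moves the median of all genes to 0.855, so a marker median of 0 or lower was out of reach. The comparison thus decides nothing about the true size of the rise. A change of remaining monocytes into macrophages, or of the neutrophils themselves, stays open and was not tested.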
